A study of Homo sapiens with 9 samples.

How the data were processed

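The libraries were made with a stranded kit (NEBNext Ultra II Directional) from 100 ng of RNA. According to the submitters' notes, reads were demultiplexed with bcl2fastq, quantified with Salmon 1.3.0 and normalized with DESeq2 1.32.0, on genome build GRCh38.p13. The signal values deposited by the authors are gene-level estimated counts divided by a size factor, with 1 column per library. For High 1 the unit was entered as other, because the authors' header gives its name also to the column of gene identifiers, but the deposited signal values are of the same kind. The notes do not state the annotation or any filter the authors applied. Whole reads could not be recovered from the deposited values, so methods that need raw counts, edgeR and DESeq2 among them, were not used.

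The file has 21778 Ensembl gene identifiers, of which 18433 were above 0 in some library. Symbols came from a gene table (19468 identifiers) and from GENCODE v29 (65 more), and 2245 stayed unnamed. All 2245 unnamed identifiers together hold 3.30% to 3.48% of the total value per library. Genes with at least 10 in at least 3 libraries were kept, 14160 in all, of which 810 are unnamed. Coordinates are from GENCODE v29 on GRCh38, counted from 1. Genes of the MHC region, such as TNF, IER3 and HSPA1A, have more than 1 copy in the assembly, and metallothioneins and histones share sequence with their paralogs, so their values are less certain.

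Values were transformed as log2(value + 1) and no further normalization was applied. The 3 comparisons, High against Low, High against NT and Low against NT, were contrasts in a single linear model with group as the only term and all 9 libraries, fitted with limma 3.58.1 (lmFit, then eBayes with a trend in the mean and robust=TRUE; statmod 1.5.0) in R 4.3.3. P-values were adjusted over the tested genes of each comparison by the Benjamini-Hochberg method, and an adjusted p below 0.05 counts as changed. Folds are 2 to the power of the difference of group means of the log2 values, with 95% intervals from the moderated standard errors. Where a list count is also given as adjusted over the list alone, the Benjamini-Hochberg step used only the members of that list. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

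Gene lists were written from general knowledge, with 658 genes in all, of which 648 were found and 585 tested. The 32 lists are iron handling, ferroptosis defence, ferroptosis execution and markers, NRF2 targets, metallothioneins, p53 targets, double-strand break repair, base excision repair, G2/M and mitosis, G1/S and replication, glycolysis, hypoxia targets, nuclear-encoded respiratory chain, mitochondrially encoded genes, citric acid cycle, cholesterol synthesis, ATF4 stress response, ER chaperones, heat shock, immediate early genes, interferon response, NF-kappaB and cytokines, apoptosis, lysosome, uptake and endocytosis, extracellular vesicle components, monocyte markers, mesothelial markers, mesenchymal and matrix, YAP targets, Wnt and beta-catenin targets, and cytosolic ribosomal proteins. Each list was tested against all other genes with camera from limma, with the preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 32 lists of a comparison. The same test with a correlation estimated from the residuals was run beside it. Lists, comparisons, thresholds and the alternatives planned for them were chosen before the data were examined.

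Genes are named by a rule that was also set beforehand. It takes the 6 higher and 6 lower genes with the largest changes among those past the test, with a mean of at least 50, a symbol, and all 3 replicates of one group beyond all 3 of the other. It adds FTH1, FTL, TFRC, CD63, HMOX1, GPX4, SLC7A11, ACSL4, CDKN1A, MKI67 and CCNB1 in every comparison. From each list past the test, or with at least 3 changed members, it adds the 3 changed members with the smallest p. The text names mainly those of lists past the test and gives the other lists as counts.

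Library totals, principal components of the tested genes and the levels of immediate early, histone and monocyte genes were used to describe the libraries. For pairing, residuals from the group means were correlated between libraries with the same replicate number, over 11799 genes with a mean of at least 100. Low and High libraries of the same number correlated at 0.188, 0.310 and 0.278, which marks them as pairs, while NT and High gave 0.0832, 0.148 and -0.00336, and NT and Low -0.128, -0.0116 and 0.0455, so NT does not pair. The fit leaves pairs out, and the replicate number as a block is an alternative.

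For the response shared by Low and High, the correlation of their changes against NT was compared with 50 simulations of unchanged groups with independent libraries. After the results were seen, 50 more were run in which Low and High libraries of the same number share the mean pair correlation. Graded genes were those past the test in High against both Low and NT, in the same direction, with the mean of Low between the other group means. Monocyte markers were compared by their mean log2 level with an exact two-sided permutation test over libraries, whose smallest p is 0.1. In a self-test with changes of known size put into simulated genes, 10, 9 and 8 of the 13960 unchanged genes passed in the 3 comparisons, and the 2 shifted lists, but none of the 30 others, were called. The simulated genes varied independently of each other, so the self-test does not show how often camera calls unshifted lists of correlated genes. They were drawn as normal noise with the fitted spread, without pairs or handling differences between libraries. The simulation thus meets the model by design, and its few calls of unchanged genes do not give the error rate in the real libraries. Changes of single genes were put only into genes with a mean log2 level above log2(50).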

Results

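RNA was sequenced from MeT-5A cells, a human mesothelial line transformed with SV40 virus, either left untreated (NT) or given FedEVs for 24 h. FedEVs are ferroptosis-dependent extracellular vesicles, here taken from THP1 cells, a human monocytic line, and marked with GFP on the vesicle protein CD63. The treated cells were sorted by flow cytometry into a GFP-low group (Low) and a GFP-high group (High), so that the groups differ in the vesicle signal the cells carried. Each group has 3 libraries, 9 in all, and the labels describe the Low and High libraries, but not the NT libraries, as sorted. The labels do not say whether the replicates were separate cultures. The values are size-factor scaled gene counts that sum to between 35.9 M and 37.7 M per library (M, mega), from an estimated 26.7 M to 45.6 M assigned reads. Of the gene identifiers, 14160 passed the filter on low values. Unless stated otherwise, a level is a group mean ± SD (n = 3) of scaled counts, a fold comes from the mean difference of log2(value + 1), and a gene is said to have risen or fallen only with a limma adjusted p below 0.05.

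The libraries parted by group, with 27.9% of the variance on the first principal component, which separated NT from Low and High, and 13.9% on the second, which separated Low from High. The third component, with 13.3%, set NT 1 (35.4) apart from NT 2 (-39.1), with the other libraries between -8.02 and 8.79. The untreated libraries thus also differed among themselves. Groups of genes with known handling or preparation responses also differed between libraries. FOS, an immediate early transcription factor, stood at 1140.3 to 1343 in the NT libraries, 3122 to 12324.5 in the Low libraries and 2321 to 9149 in the High libraries, with the highest values in Low 3 and High 3. The mean log2 level of replication-dependent histone genes, whose mRNAs lack poly(A) tails, was 7.88 in NT 1 and 7.63 in NT 2 against 5.64 in NT 3, and between 5.16 and 5.47 in the Low and High libraries.

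High against Low asks how cells that took up more vesicle signal differed from treated cells that took up less. Genes of mitosis were higher in High. PLK1, a kinase that drives mitotic entry and exit (chromosome 16, 23677656 to 23690367, GRCh38), stood at 11501 ± 192 in High and 5169 ± 106 in Low (SD, n = 3), a rise of 2.22-fold (95% interval 2.10 to 2.35). AURKA, the centrosomal mitotic kinase, was 2.19-fold (95% interval 2.06 to 2.33) higher, the topoisomerase TOP2A 1.91-fold (95% interval 1.81 to 2.01) higher, and the spindle protein FAM83D 2.27-fold (95% interval 2.15 to 2.39) higher. All 28 measured members of the G2/M and mitosis list rose, with a median log2 change of 0.75 (camera adjusted p = 3.18e-50, 0.00976 with an estimated correlation), among them CCNB1, the mitotic cyclin, from 4450.3 ± 251 to 8408 ± 279.8, and MKI67, a proliferation antigen, from 22285 ± 373 to 34933 ± 569.8. The opposite held for the G1/S and replication list, of which 16 of 22 members fell, none rose and 6 did not pass, or 19 fell when adjusted over the list alone (median log2 -0.35; camera adjusted p = 1.48e-18, 0.00976 with an estimated correlation). MCM6, a subunit of the replicative helicase (chromosome 2, 135839626 to 135876426), was 1.62-fold (95% interval 1.53 to 1.71) lower in High, at 5498 ± 111 against 8902 ± 135. E2F1, the transcription factor of S-phase entry, was 1.52-fold lower and MCM5 1.52-fold lower.

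Interferon and inflammatory genes were higher in High than in Low. 10 of 22 members of the interferon response list rose, none fell and 12 did not pass, with 13 risen when adjusted over the list alone (median log2 0.23; camera adjusted p = 7.14e-08, 0.274 with an estimated correlation). OASL, an interferon-induced antiviral protein (chromosome 12, 121019111 to 121039242), stood at 3394 ± 64.6 in High and 2538 ± 92.1 in Low, a rise of 1.34-fold (95% interval 1.249 to 1.43). IFIT3 and HERC5, which are also interferon-induced, were 1.29-fold and 1.29-fold higher. In the NF-kappaB and cytokine list, 3 of 15 members rose and 12 did not pass, the same numbers as when adjusted over the list alone (median log2 0.27; camera adjusted p = 0.00630, 0.315 with an estimated correlation). The list's adjusted p was 0.0662 without Low 1 and 0.0508 without High 3. The 3 members were the mitochondrial superoxide dismutase SOD2 (1.27-fold (95% interval 1.19 to 1.35)), the adhesion molecule ICAM1 (1.22-fold (95% interval 1.13 to 1.31)) and the NF-kappaB subunit RELB (1.37-fold (95% interval 1.16 to 1.61)). RELB had an adjusted p of 0.0315, which rose to 0.111, 0.0683 and 0.101 without Low 1, 2 or 3 and to 0.0973, 0.0954 and 0.0957 without High 1, 2 or 3.

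Genes of cholesterol synthesis, YAP targets, hypoxia and glycolysis were lower in High by small amounts. Of the cholesterol synthesis list, 7 of 20 members fell and 13 did not pass, or 9 fell when adjusted over the list alone (median log2 -0.12; camera adjusted p = 5.84e-06, 0.274 with an estimated correlation). The squalene epoxidase SQLE was 1.17-fold lower, at 5151 ± 125 against 6033 ± 92.8, the sterol sensor INSIG1 1.22-fold lower, and the lanosterol synthase LSS 1.16-fold lower. Of the YAP targets, 3 of 15 fell and 12 did not pass, or 4 fell when adjusted over the list alone (median log2 -0.17; camera adjusted p = 2.85e-04, 0.294 with an estimated correlation). NT5E, the ecto-nucleotidase CD73, was 1.27-fold (95% interval 1.17 to 1.39) lower, at 2439.5 ± 98.3 against 3109 ± 194. ANKRD1 was 1.45-fold lower (adjusted p = 0.0175, and 0.0739, 0.0559, 0.0572 and 0.0734 without Low 1, Low 2, High 1 or High 2), and CRIM1 1.19-fold lower (adjusted p = 0.0152, and 0.0620, 0.0598, 0.0630 and 0.0634 without Low 1, Low 3, High 2 or High 3). Of the hypoxia targets, 2 of 15 fell on either adjustment (median log2 -0.13; camera adjusted p = 0.0147, 0.294 with an estimated correlation, 0.0898 without Low 2 and 0.0918 without High 1), the mitophagy receptor BNIP3L by 1.26-fold among them. Of the glycolysis list, the lactate exporter SLC16A3 fell, 1.16-fold, and 18 of 19 members did not pass, with 2 lower when adjusted over the list alone (median log2 -0.08; camera adjusted p = 0.0147, 0.294 with an estimated correlation, 0.0615 without High 2 and 0.0855 after quantile normalization).

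The genes with the largest folds included others outside these lists. Among those higher in High, PIF1, a DNA helicase, was 2.95-fold (95% interval 2.70 to 3.23) higher, the dehydrogenase DHRS2 2.76-fold (95% interval 2.36 to 3.23) higher, and TNFRSF9, a costimulatory receptor of the TNF receptor family, 2.55-fold (95% interval 1.90 to 3.44) higher, at 202 ± 21.7 against 78.7 ± 10.8. ARHGEF26 was 3.02-fold (95% interval 1.84 to 4.97) higher with an adjusted p of 0.0137, and 0.0540, 0.0533, 0.0653 and 0.0568 without Low 1, Low 3, High 1 or High 2. Among those lower, CLN8, an endoplasmic reticulum protein mutated in a neuronal storage disease (chromosome 8, 1755778 to 1801711), stood at 98.1 ± 16.1 against 302 ± 54.8, 3.06-fold (95% interval 2.24 to 4.18) lower. SAMD5 was 2.49-fold lower, the calcium-binding protein NCALD 1.97-fold lower, and the gap junction protein GJA1 1.92-fold lower. RNF152, a lysosomal ubiquitin ligase, and the glycosyltransferase B3GNT4 were 1.99-fold and 1.98-fold lower. The adjusted p of RNF152 was 0.0207, and 0.0830, 0.0797, 0.0807 and 0.0528 without Low 1, Low 2, High 1 or High 2. That of B3GNT4 was 0.0259, and 0.0824, 0.0757, 0.0856, 0.0829 and 0.0767 without Low 1, Low 2, Low 3, High 1 or High 2.

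Of the iron and ferroptosis genes named in every comparison, none passed in High against Low. TFRC, the transferrin receptor, stood at 2305 ± 42.2 in High and 2432 ± 44.5 in Low (adjusted p = 0.550), and the ferritin chains FTH1 and FTL, the lipid peroxide reductase GPX4, the cystine transporter subunit SLC7A11, the lipid ligase ACSL4, the heme oxygenase HMOX1, the vesicle protein CD63 and the cell cycle inhibitor CDKN1A did not pass either, with folds of at most 1.16. In the iron handling list 2 members rose and 2 fell of 22. The ferrireductase STEAP3 fell 1.322-fold and the mitochondrial iron importer SLC25A37 1.19-fold (adjusted p = 0.0147, and 0.0635, 0.0613 and 0.0616 without Low 2, Low 3 or High 1). The metal importer SLC39A8 rose 1.39-fold (adjusted p = 0.0259, and 0.0826, 0.0997, 0.0910, 0.0695 and 0.0815 without Low 1, Low 2, High 1, High 2 or High 3). SLC40A1, the iron exporter, was outside the naming rule and was picked out after its values were seen. It rose 3.69-fold (95% interval 1.74 to 7.83), from 5.45 ± 2.20 to 23.8 ± 12.1, levels close to the filter, with an adjusted p of 0.0459. That p was above 0.05 without any one library except NT 1 and High 2, at 0.0577 and 0.0532 without NT 2 or NT 3, 0.145, 0.0866 and 0.0749 without Low 1, 2 or 3, and 0.180 and 0.132 without High 1 or High 3. It was also above 0.05 with the replicate block (0.0853), with the block within the sorted libraries (0.0926), after quantile normalization (0.0762), with only the 2 groups (0.0572), a pseudocount of 10 (0.0564), robust=FALSE (0.0541) or the immediate early covariate (0.0627), so the rise of SLC40A1 rests on the settings chosen. The counts were 0 higher and 3 lower of 16 for ferroptosis defence, 0 higher and 4 lower of 21 for NRF2 targets, 0 higher and 1 lower of 23 for p53 targets, 2 higher and 5 lower of 26 for double-strand break repair and 1 higher and 1 lower of 16 for base excision repair. In the base excision repair list, the uracil glycosylase UNG was 1.51-fold lower and the glycosylase NEIL3 1.39-fold higher. The counts were 2 higher and 5 lower of 19 for mesenchymal and matrix genes, 2 higher and 1 lower of 10 for mesothelial markers, 2 higher and 1 lower of 16 for the ATF4 stress response, 0 higher and 3 lower of 21 for uptake and endocytosis and 1 higher and 1 lower of 11 for heat shock. A single member rose of the immediate early genes (18 measured), of extracellular vesicle components (17) and of Wnt and beta-catenin targets (13), and a single member fell of apoptosis (17). No member passed in the lists of ferroptosis execution (10 measured), metallothioneins (4), nuclear-encoded respiratory chain (40), mitochondrially encoded genes (13), citric acid cycle (17), ER chaperones (15), lysosome (22), monocyte markers (9) and cytosolic ribosomal proteins (48). The camera adjusted p of these 24 lists ranged from 0.144 to 0.846. With replicate number as a block among the Low and High libraries, the immediate early list was lower in High (median log2 -0.19, adjusted p = 6.05e-04, against 0.699 without the block). It did not pass with the planned block over all 9 libraries (0.563) or with an estimated correlation (0.931), and its mean log2 level was not lower in each pair (10.46 in Low 2 and 10.50 in High 2). Without the filter on low values, monocyte markers passed as higher (adjusted p = 0.0232, against 0.218 with the filter). Median, mean and test differed in sign for iron handling, NRF2 targets, the respiratory chain, ER chaperones and apoptosis.

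Across all genes, 937 of 14160 passed in High against Low, 418 higher and 519 lower, and 28 of them changed by at least 2-fold, 23 higher and 5 lower. The count was 545, 582 and 556 without Low 1, 2 or 3, and 530, 554 and 585 without High 1, 2 or 3. The ranges of the groups did not overlap for 4395 genes (31.0%), where chance gives 10%. Changes of 1.5-fold were recovered in 80% of simulated genes with a level above 50 and changes of 2-fold in 96%, so smaller changes were missed more often. Recovery in tested genes below that level was not simulated.

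**Figure D1:**
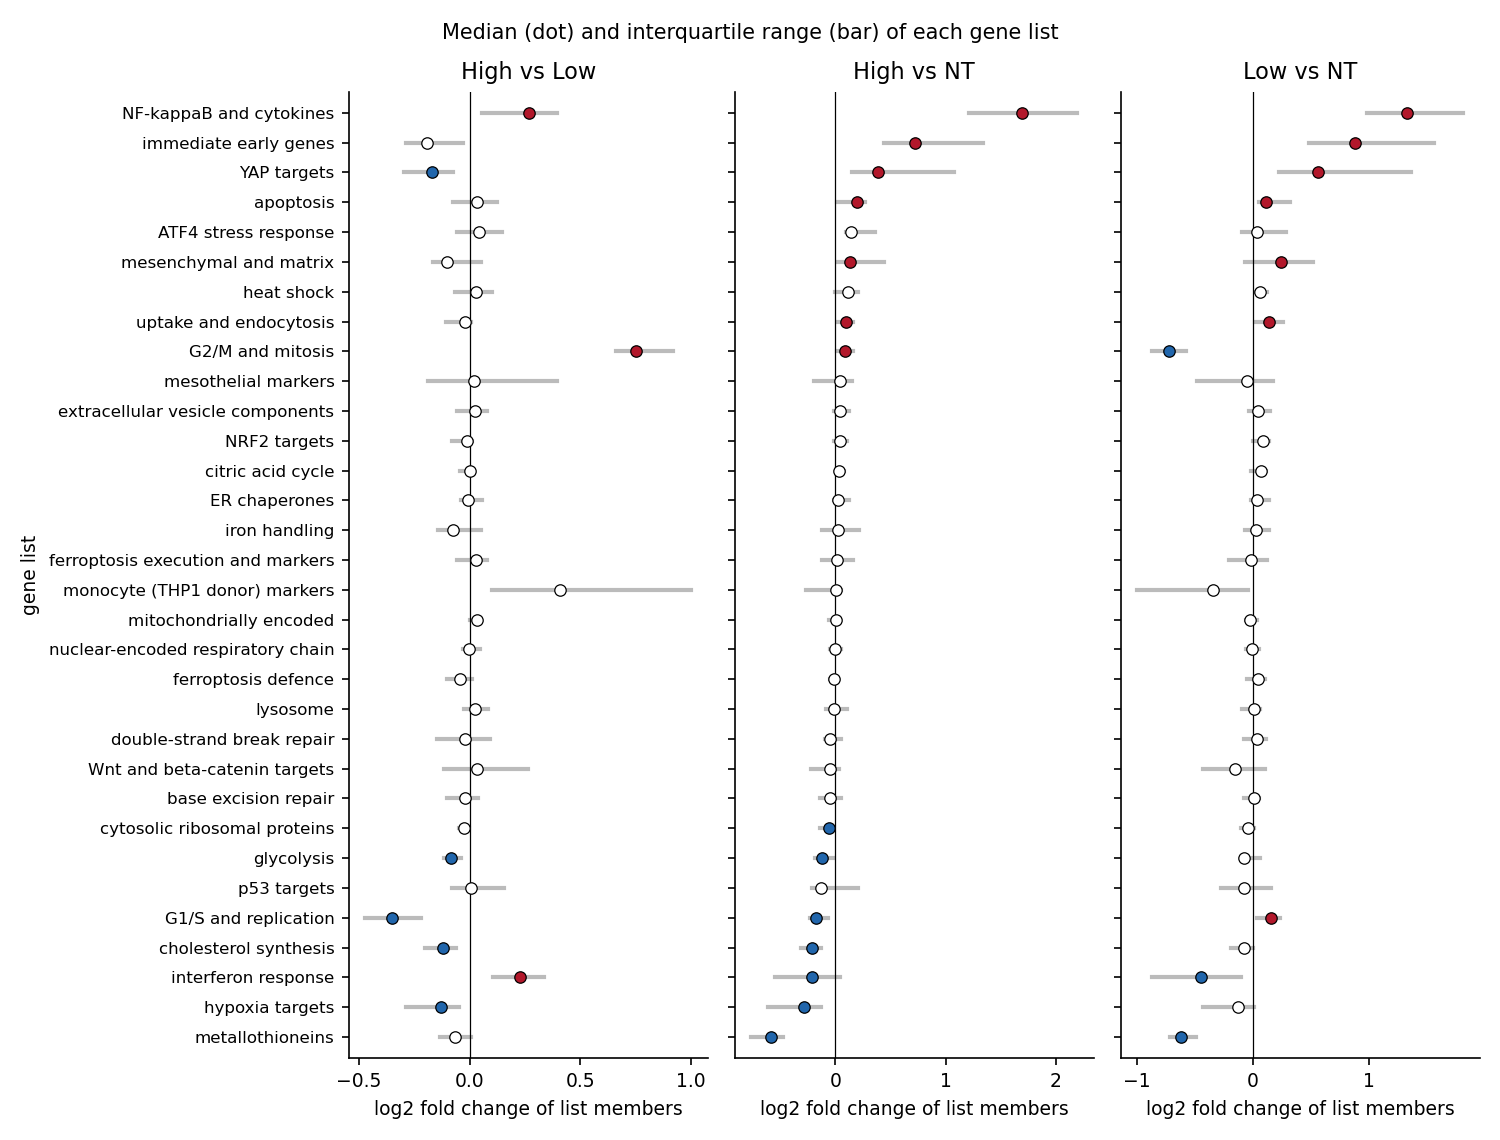
Median log2 fold change (dot) and interquartile range (bar) of the measured members of each fixed gene list, for High against Low, High against NT and Low against NT, n = 3 libraries per group. Filled red and blue dots are lists with a camera adjusted p below 0.05 that were higher or lower, and the horizontal scales differ between the panels. The G2/M and mitosis list lies at 0.75 in High against Low and at -0.72 in Low against NT, and the NF-kappaB and cytokine list at 1.69 in High against NT.

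High against NT asks how the cells with the most vesicle signal differed from untreated cells. As NT is not described as sorted, the vesicles and the sort differ together in both comparisons with NT. Inflammatory genes were among the largest rises. IL32, a proinflammatory cytokine (chromosome 16, 3065297 to 3082192), rose from 76.5 ± 23.5 in NT to 1342 ± 5.68 in High (SD, n = 3), or 17.8-fold (95% interval 13.9 to 22.9). VCAM1, a leukocyte adhesion molecule, rose 15.2-fold (95% interval 11.01 to 21.0) from 13.9 ± 3.13 to 223 ± 26.4, the complement component C3 11.6-fold (95% interval 9.38 to 14.3), the receptor TNFRSF9 15.2-fold (95% interval 11.3 to 20.4) and the lysosomal protease CTSS 13.2-fold (95% interval 8.06 to 21.6). Of the NF-kappaB and cytokine list, 11 of 15 members rose, none fell and 4 did not pass, with 14 risen when adjusted over the list alone (median log2 1.69; camera adjusted p = 2.16e-12, 0.0730 with an estimated correlation). RELB (chromosome 19, 45001430 to 45038198) rose 10.5-fold (95% interval 8.90 to 12.4), from 171 ± 32.3 to 1787 ± 5.99, ICAM1 3.24-fold (95% interval 3.01 to 3.49) and NFKBIA, the inhibitor that NF-kappaB itself induces, 2.79-fold (95% interval 2.53 to 3.08).

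TFRC, which brings transferrin-bound iron into the cell (chromosome 3, 196027183 to 196082189), fell 3.97-fold (95% interval 3.60 to 4.37), from 9176 ± 934 in NT to 2305 ± 42.2 in High. The ferritin subunits FTH1 and FTL, which store iron, were at 50284 ± 2438 and 23040.2 ± 324 in High against 46176 ± 2235 and 22856 ± 1692 in NT and did not pass (adjusted p = 0.135 and 0.895). HMOX1, which releases iron from heme, rose 1.43-fold (95% interval 1.29 to 1.60), and the zinc and iron importer SLC39A14 rose 1.301-fold. GPX4, SLC7A11 and ACSL4 did not pass, with log2 changes of 0.01, 0.01 and 0.13 (SE 0.0547, 0.123 and 0.0574). CD63, the protein that carries GFP on the vesicles, rose 1.15-fold. Metallothioneins, metal-binding proteins whose genes share sequence, with reads that can be split between them, were lower. 3 of 4 measured members fell, or 4 when adjusted over the list alone (median log2 -0.59; camera adjusted p = 4.18e-04, 0.119 with an estimated correlation). MT2A fell from 5183 ± 332 to 3210.1 ± 79.9, 1.61-fold (95% interval 1.48 to 1.75), MT1E 1.97-fold and MT1X 1.40-fold.

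YAP targets and mesenchymal genes were higher in High than in NT. 10 of 15 YAP targets rose and 5 did not pass, the same numbers as when adjusted over the list alone (median log2 0.39; camera adjusted p = 8.52e-08, 0.119 with an estimated correlation). CCN2, a matrix-associated growth factor, rose 2.98-fold (95% interval 2.57 to 3.45) from 5309 ± 371 to 15850.2 ± 1821, ANKRD1 2.61-fold and NT5E 2.08-fold. Of the mesenchymal and matrix list, 7 of 19 rose, 1 fell and 11 did not pass, with 9 risen when adjusted over the list alone (median log2 0.13; camera adjusted p = 7.26e-04, 0.0730 with an estimated correlation). ACTA2, the smooth muscle actin of myofibroblasts, rose 2.35-fold (95% interval 2.20 to 2.52), from 5851 ± 326 to 13765 ± 416, the matrix protein POSTN 1.67-fold and N-cadherin, CDH2, 1.37-fold. Of the uptake and endocytosis list, 7 of 21 rose and 2 fell, with 10 risen when adjusted over the list alone (median log2 0.10; camera adjusted p = 0.0138, 0.268 with an estimated correlation and 0.138 after quantile normalization). The integrin subunits ITGB3, ITGAV and ITGB5 rose 1.81-fold, 1.63-fold and 1.20-fold. Of the apoptosis list, 6 of 17 rose and none fell, with 7 risen when adjusted over the list alone (median log2 0.19; camera adjusted p = 0.00985, 0.370 with an estimated correlation), the survival proteins BCL2L1 and MCL1 by 1.20-fold and 1.34-fold and the proapoptotic BID by 1.22-fold.

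Interferon, hypoxia, cholesterol, glycolysis and replication genes were lower. Of the interferon response list, 9 of 22 fell, 3 rose and 10 did not pass, with 10 fallen when adjusted over the list alone (median log2 -0.21; camera adjusted p = 6.90e-04, 0.370 with an estimated correlation). OASL fell 1.75-fold (95% interval 1.64 to 1.88), from 5949 ± 235 to 3394 ± 64.6, ISG15 1.60-fold and IFIT1 1.49-fold. Of the hypoxia targets, 8 of 15 fell and 2 rose, with 11 and 3 when adjusted over the list alone (median log2 -0.29; camera adjusted p = 4.18e-04, 0.111 with an estimated correlation). The carbonic anhydrase CA9 fell 3.31-fold (95% interval 2.52 to 4.33) from 245 ± 27.1 to 73.2 ± 5.66, the kinase PDK1 1.64-fold and the mitophagy receptor BNIP3 1.57-fold. Of the cholesterol synthesis list, 13 of 20 fell and 1 rose, with 15 fallen when adjusted over the list alone (median log2 -0.21; camera adjusted p = 1.45e-07, 0.111 with an estimated correlation). HMGCS1, an early enzyme of the pathway, fell 1.31-fold, MSMO1 1.36-fold and SQLE 1.23-fold. In the glycolysis list 7 of 19 fell and 1 rose, with 9 fallen when adjusted over the list alone (median log2 -0.12; camera adjusted p = 0.00118, 0.129 with an estimated correlation). The aldolase ALDOC fell 1.76-fold, SLC16A3 1.22-fold and the isomerase GPI 1.14-fold. In the G1/S list 13 of 22 fell on either adjustment (median log2 -0.18; camera adjusted p = 8.52e-08, 0.0730 with an estimated correlation), the helicase subunits MCM2 and MCM7 by 1.247-fold and 1.13-fold and the licensing factor CDT1 by 1.26-fold.

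Mitotic genes in High lay close to NT. 8 of 28 members of the G2/M list rose, 1 fell and 19 did not pass, with 9 and 2 when adjusted over the list alone (median log2 0.09; camera adjusted p = 0.0138, 0.506 with an estimated correlation and 0.396 after quantile normalization). KIF23, a kinesin of cytokinesis, rose 1.23-fold and the kinase AURKB 1.21-fold, while MKI67 and CCNB1 did not pass (adjusted p = 0.175 and 0.0782). Of the immediate early genes, 4 of 18 rose and none fell, with 5 risen when adjusted over the list alone (median log2 0.72; camera adjusted p = 4.18e-04, 0.535 with an estimated correlation). FOSL1, a partner of JUN, rose 1.254-fold (95% interval 1.13 to 1.40). JUNB rose 2.14-fold (95% interval 1.44 to 3.18) with an adjusted p of 0.0244, and 0.0571, 0.0720, 0.0681, 0.0699 and 0.0522 without NT 1, NT 2, NT 3, High 2 or High 3. In the cytosolic ribosomal protein list 3 of 48 members fell, and none when adjusted over the list alone (median log2 -0.06; camera adjusted p = 0.00118, 0.677 with an estimated correlation and 0.267 without NT 1). RPSA, RPL12 and RPL15 fell 1.14-fold each, with the adjusted p of each above 0.05 without some single libraries. RPSA reached 0.0604, 0.0519 and 0.0748 without High 1, 2 or 3, RPL12 0.0604 and 0.0982 without High 1 or High 2, and RPL15 0.0745, 0.0642, 0.0977 and 0.106 without NT 1, NT 3, High 1 or High 2.

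Among the genes with the largest falls was TIMP3, an inhibitor of matrix metalloproteinases (chromosome 22, 32801701 to 32863043). It fell 6.85-fold (95% interval 5.66 to 8.29), from 651 ± 21.3 to 94.2 ± 4.11. The homeobox genes HOXB3 (chromosome 17, 48548870 to 48604912) and HOXB2 fell 5.67-fold (95% interval 3.29 to 9.76) and 4.19-fold (95% interval 2.51 to 7.00), and the extracellular protein EMILIN3 fell 4.01-fold (95% interval 2.87 to 5.599). The protocadherin PCDHAC2 fell 4.04-fold (95% interval 1.80 to 9.09) with an adjusted p of 0.0260, and 0.0544, 0.0926 and 0.0911 without NT 2, High 1 or High 2 and 0.0528 with a replicate block. In the remaining lists the counts were 5 higher and 3 lower of 22 for iron handling, 0 higher and 1 lower of 16 for ferroptosis defence, 2 higher and 1 lower of 10 for ferroptosis execution, 3 higher and 3 lower of 21 for NRF2 targets, 4 higher and 6 lower of 23 for p53 targets, 2 higher and 1 lower of 26 for double-strand break repair and 0 higher and 1 lower of 16 for base excision repair. The reductase AKR1B10 fell 2.80-fold and the p53 target MDM2 1.43-fold, while CDKN1A, another p53 target, stood at 3977 ± 481 against 4238 ± 57.4 and did not pass. The counts were 1 higher and 3 lower of 10 for mesothelial markers, 4 higher and 1 lower of 22 for the lysosome, 4 higher and 1 lower of 11 for heat shock, 3 higher and 0 lower of 17 for vesicle components, 3 higher and 1 lower of 16 for the ATF4 stress response, 1 higher and 0 lower of 15 for ER chaperones, 0 higher and 2 lower of 13 for Wnt targets, 1 higher and 1 lower of 17 for the citric acid cycle, 1 higher and 1 lower of 40 for the respiratory chain, 0 higher and 0 lower of 13 for mitochondrially encoded genes and 0 higher and 1 lower of 9 for monocyte markers. The tetraspanin CD82 rose 2.08-fold (95% interval 1.86 to 2.33). The camera adjusted p of these 18 lists ranged from 0.0644 to 0.864, and that of the ATF4 stress response, 0.0644, was 0.0375 with a replicate block, 0.0241 without the filter on low values, and 0.0444, 0.0408, 0.0346 and 0.0417 without Low 1, Low 2, Low 3 or High 2. Vesicle components passed as higher without the filter (0.0361) and without NT 1 (0.0264), and mitochondrially encoded genes without NT 2 (0.0498). With an estimated correlation the adjusted p of these 3 lists was 0.405, 0.370 and 0.958. Median, mean and test differed in sign for iron handling, ferroptosis execution, NRF2 targets, the respiratory chain, monocyte markers and mesothelial markers.

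Across all genes, 2416 passed in High against NT, 1412 higher and 1004 lower, with a median fold of 1.26, and 124 rose and 183 fell by at least 2-fold. After quantile normalization the split was 1153 higher and 1253 lower. The count was 1609 without High 1 and 1607 without High 3. The group ranges did not overlap for 4888 genes (34.5%), where chance gives 10%. Of simulated changes of 1.5-fold and 2-fold in genes with a level above 50, 72% and 100% were recovered.

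**Figure D2:**
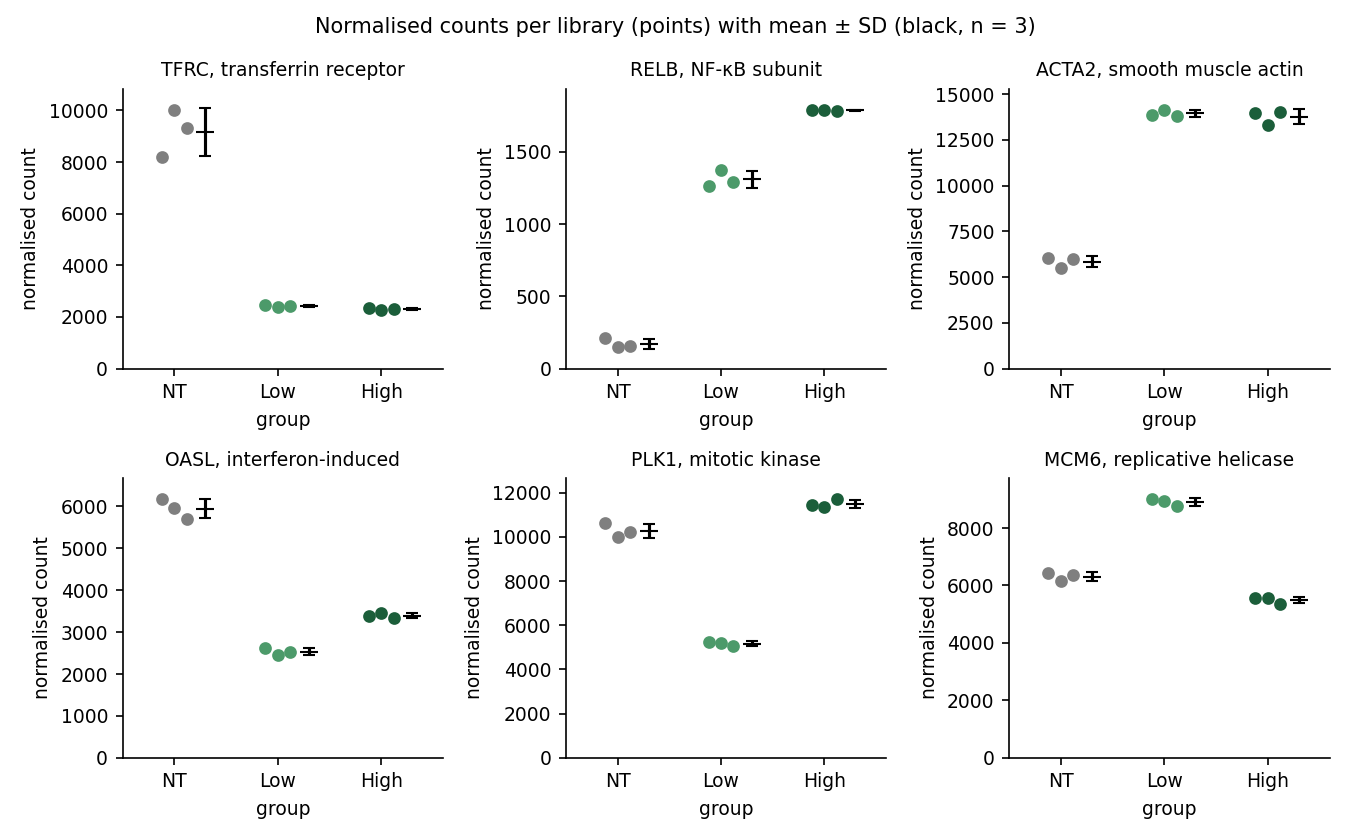
Scaled counts per library (points) with the group mean ± SD (bars, n = 3) of TFRC, RELB, ACTA2, OASL, PLK1 and MCM6 in NT, Low and High, on linear axes that start at 0. TFRC lies at 9176 ± 934 in NT and at 2432 ± 44.5 and 2305 ± 42.2 in Low and High, while PLK1 is lower in Low (5169 ± 106) than in NT (10274 ± 329) and High (11501 ± 192).

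Low against NT asks how treated cells with little vesicle signal differed from untreated cells. Inflammatory genes rose here as well. IL32 rose 12.0-fold (95% interval 9.35 to 15.4) to 904 ± 47.3, the chemokine CCL2 8.20-fold (95% interval 6.71 to 10.0) from 109 ± 5.33 to 914 ± 187 (SD, n = 3), VCAM1 8.40-fold (95% interval 6.09 to 11.6), CTSS 8.74-fold (95% interval 5.34 to 14.3), the vasoconstrictor EDN1 8.40-fold (95% interval 6.38 to 11.1) and the hyaluronan-degrading CEMIP 9.04-fold (95% interval 5.56 to 14.7). The chemokine CXCL2 rose 10.2-fold (95% interval 2.97 to 34.9), with an adjusted p of 0.0152, and 0.0562 and 0.0516 without NT 1 or NT 2. With the immediate early level as a covariate the rise of CXCL2 was 2.47-fold (adjusted p = 0.136). Of the NF-kappaB and cytokine list, 11 of 15 members rose, none fell and 4 did not pass, with 12 risen when adjusted over the list alone (median log2 1.322; camera adjusted p = 1.47e-09, 0.0873 with an estimated correlation). RELB rose 7.69-fold (95% interval 6.52 to 9.07) and ICAM1 2.66-fold (95% interval 2.47 to 2.87).

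Mitotic genes fell in Low. All 28 measured members of the G2/M list were lower than in NT (median log2 -0.72; camera adjusted p = 3.63e-29, 0.0584 with an estimated correlation). TOP2A fell 2.01-fold (95% interval 1.90 to 2.11), from 20470.1 ± 307 to 10208 ± 317, AURKA 2.06-fold (95% interval 1.94 to 2.19), PLK1 1.99-fold (95% interval 1.88 to 2.10), CCNB1 1.72-fold and MKI67 1.45-fold. Of the G1/S list, 13 of 22 rose and 1 fell, the same numbers as when adjusted over the list alone (median log2 0.16; camera adjusted p = 1.79e-04, 0.158 with an estimated correlation). MCM6 rose 1.41-fold (95% interval 1.34 to 1.49), MCM5 1.34-fold and E2F1 1.302-fold.

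Interferon genes and metallothioneins were lower, and YAP and matrix genes higher. Of the interferon response list, 14 of 22 fell and 3 rose, with 15 fallen when adjusted over the list alone (median log2 -0.44; camera adjusted p = 3.19e-07, 0.190 with an estimated correlation). OASL fell 2.34-fold (95% interval 2.19 to 2.51), HERC5 1.90-fold and IFIT1 1.86-fold. Of the metallothioneins, 3 of 4 fell on either adjustment (median log2 -0.62; camera adjusted p = 0.00242, 0.190 with an estimated correlation), MT2A by 1.58-fold (95% interval 1.45 to 1.72). Of the YAP targets, 12 of 15 rose, or 13 when adjusted over the list alone (median log2 0.56; camera adjusted p = 1.47e-09, 0.136 with an estimated correlation). CCN2 rose 3.85-fold (95% interval 3.32 to 4.47) to 20484 ± 2041, ANKRD1 3.79-fold (95% interval 3.20 to 4.50) and NT5E 2.65-fold. Of the mesenchymal and matrix list, 12 of 19 rose and 2 fell on either adjustment (median log2 0.24; camera adjusted p = 1.77e-04, 0.0619 with an estimated correlation). ACTA2 rose 2.39-fold (95% interval 2.23 to 2.55) to 13945 ± 177, POSTN 1.96-fold and the collagen COL3A1 1.46-fold. Of uptake and endocytosis, 9 of 21 rose and 3 fell, with 10 and 3 when adjusted over the list alone (median log2 0.14; camera adjusted p = 0.00693, 0.211 with an estimated correlation and 0.0980 after quantile normalization), ITGB3 by 2.20-fold. Of apoptosis, 7 of 17 rose on either adjustment (median log2 0.11; camera adjusted p = 0.0103, 0.383 with an estimated correlation), BCL2 by 1.91-fold (95% interval 1.66 to 2.20). Of the immediate early genes, 5 of 18 rose, or 8 when adjusted over the list alone (median log2 0.88; camera adjusted p = 0.00147, 0.544 with an estimated correlation). JUNB rose 2.34-fold, and JUN 2.95-fold with an adjusted p of 0.0230, which was 0.0585, 0.0659, 0.0596 and 0.0653 without NT 1, NT 2, NT 3 or Low 2.

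TFRC fell 3.76-fold (95% interval 3.41 to 4.14) in Low, to 2432 ± 44.5. FTH1, FTL, GPX4, SLC7A11, ACSL4 and CDKN1A did not pass, with FTH1 at 50597 ± 2899.7 and GPX4 at 10337 ± 209.6. CD63 rose 1.18-fold and HMOX1 1.24-fold, and the ferrireductase STEAP3 rose 1.63-fold (95% interval 1.47 to 1.80). Outside the lists, TIMP3 fell 8.44-fold (95% interval 6.97 to 10.2), ARHGEF26 11.02-fold (95% interval 6.70 to 18.1), HOXB3 6.07-fold (95% interval 3.52 to 10.5), EMILIN3 5.86-fold (95% interval 4.20 to 8.19), PCDHAC2 5.51-fold (95% interval 2.45 to 12.4) and DHRS2 5.16-fold (95% interval 4.41 to 6.04). The counts in the remaining lists were 6 higher and 2 lower of 22 for iron handling, 2 higher and 1 lower of 16 for ferroptosis defence, 2 higher and 2 lower of 10 for ferroptosis execution, 5 higher and 1 lower of 21 for NRF2 targets, 5 higher and 9 lower of 23 for p53 targets, 4 higher and 3 lower of 26 for double-strand break repair, 2 higher and 1 lower of 16 for base excision repair and 3 higher and 5 lower of 15 for hypoxia targets. They were 3 higher and 4 lower of 19 for glycolysis, 2 higher and 6 lower of 20 for cholesterol synthesis, 4 higher and 1 lower of 17 for the citric acid cycle, 1 higher and 1 lower of 40 for the respiratory chain, 0 higher and 0 lower of 13 for mitochondrially encoded genes, 3 higher and 1 lower of 16 for the ATF4 stress response, 5 higher and 2 lower of 15 for ER chaperones and 3 higher and 0 lower of 11 for heat shock. They were 1 higher and 3 lower of 22 for the lysosome, 4 higher and 0 lower of 17 for vesicle components, 0 higher and 1 lower of 9 for monocyte markers, 1 higher and 2 lower of 10 for mesothelial markers, 0 higher and 3 lower of 13 for Wnt targets and 0 higher and 4 lower of 48 for cytosolic ribosomal proteins. The p53 target GDF15 fell 2.50-fold (95% interval 1.84 to 3.40), the hypoxia target CA9 2.95-fold (95% interval 2.25 to 3.87), the keratin KRT5 4.11-fold (95% interval 2.67 to 6.32) and the Wnt antagonist DKK1 1.79-fold. The camera adjusted p of these 22 lists ranged from 0.0859 to 0.919. After quantile normalization 4 of them passed as lower, glycolysis (adjusted p = 0.0114), cholesterol synthesis (0.00533), the lysosome (0.0355) and cytosolic ribosomal proteins (1.10e-06). Cholesterol synthesis also passed without NT 1 (0.0474), ribosomal proteins without NT 2 (2.59e-04), and monocyte markers, as lower, without NT 3 (0.0489) and without the filter on low values (0.0122). With an estimated correlation the adjusted p of these 5 lists was 0.508, 0.508, 0.787, 0.802 and 0.320. Median, mean and test differed in sign for iron handling, NRF2 targets, base excision repair, the respiratory chain and the lysosome.

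Across all genes, 3220 passed in Low against NT, 1842 higher and 1378 lower, with a median fold of 1.27, and 157 rose and 279 fell by at least 2-fold. After quantile normalization the split was 1443 higher and 1557 lower. The group ranges did not overlap for 5381 genes, where chance gives 10%. Of simulated changes of 1.5-fold and 2-fold in genes with a level above 50, 76% and 98% were recovered.

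Low and High were also compared with each other through their changes against NT. Many genes changed the same way in both, with 1032 higher in both and 565 lower in both, where independent lists would share 184 and 97.7. TFRC, TIMP3 and HOXB3 fell in both, and IL32, RELB, CCL2, CCN2 and ACTA2 rose in both. Across genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.712, where unchanged groups simulated against the same 3 NT libraries gave 0.501 on average (0.4001 to 0.591 in 50 simulations). These libraries were simulated without the pairing of Low and High by number, and with a pair correlation of 0.259 the average was 0.624 (0.565 to 0.678). The covariance was 0.178 against 0.0459 simulated without pairs. The observed correlation had a jackknife SE of 0.0785 and was 0.676 to 0.762 when 1 library was left out. Most of the correlation, and part of the overlap of calls, can come from the shared NT libraries, which are too few to split, and from the pairs.

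Against NT, 50 genes rose in one treated group and fell in the other, 27 of them higher in High, and all 50 also passed in High against Low. They include 8 members of the G2/M list, such as PLK1, KIF23 and AURKB, which rose in High and fell in Low, and 8 of the G1/S list, such as MCM2, MCM5, MCM6 and E2F1, which fell in High and rose in Low. Another 122 genes were graded, with the Low mean between NT and High and the difference of High from both NT and Low past the test, 49 rising and 73 falling. Of these, 50 also passed in Low against NT in the same direction, 21 rising and 29 falling, and 72 did not pass there, so for them a step between NT and Low is not shown. VCAM1 (13.9 ± 3.13 in NT, 123 ± 19.6 in Low and 223 ± 26.4 in High), C3 (794 ± 131, 5092 ± 466 and 9161 ± 1102), TNFRSF9, RELB and ICAM1 rose in this order and passed in all 3 comparisons. CLN8 and NCALD fell in High only, with 302 ± 54.8 and 253 ± 7.78 in Low against 317 ± 82.4 and 268 ± 10.95 in NT (adjusted p = 0.890 and 0.686). The graded count was 197 without NT 1, 58, 68 and 64 without Low 1, 2 or 3, and 63, 61 and 67 without High 1, 2 or 3. CXCL2, EDN1, CCN2, ANKRD1 and NT5E rose in both, with a mean that was higher in Low than in High. In High against Low, ANKRD1 and NT5E passed as lower, while CXCL2 and CCN2 did not pass.

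**Figure D3:**
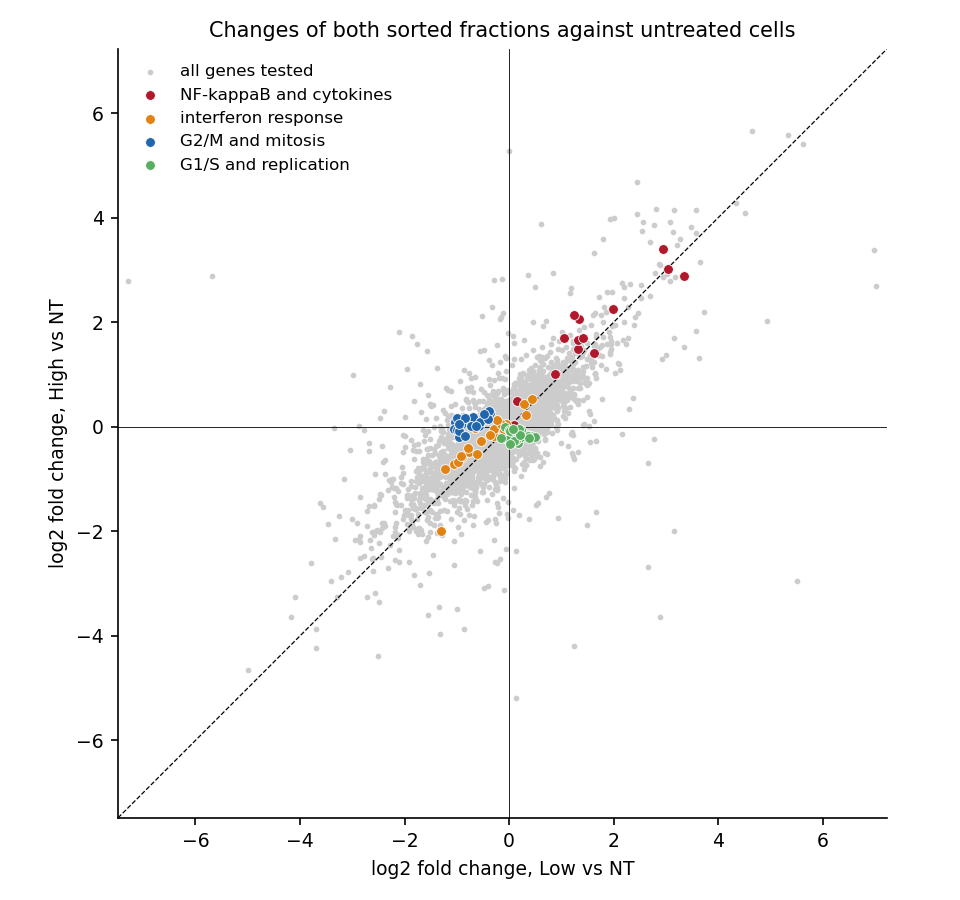
Log2 fold change of each gene in Low against NT (horizontal axis) and in High against NT (vertical axis), n = 3 libraries per group, with all tested genes in grey and the members of the NF-kappaB, interferon, G2/M and G1/S lists in colour. The dashed line marks equal changes, and both axes share the NT libraries. The NF-kappaB members lie to the upper right (medians 1.322 and 1.69), the G2/M members to the left near 0 on the vertical axis (-0.72 and 0.09).

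Most marker genes of monocytes, the type of cell the vesicles came from, stayed low in all groups. Of the 30 markers, 19 were below 10 in every library, and LYZ, SPI1, TYROBP and S100A8, which monocytic cells express strongly, were at or near 0. CD14, which the untreated cells already expressed, stood at a mean of 658 in NT, 519 in Low and 421.5 in High. CORO1A (257, 248 and 266 in the same order) and LAPTM5 (146, 116 and 150) were also expressed in the untreated cells. The mean log2 level of the 30 markers was 0.44 higher in High than in Low (exact two-sided permutation p = 0.1), differed by -0.09 between High and NT (exact permutation p = 0.8; a difference of 0.04 without NT 2), and by -0.53 between Low and NT (exact permutation p = 0.1). With a pseudocount of 0.1 in place of 1 these differences were 0.86, -0.23 and -1.08. With 3 libraries against 3, 0.1 is the smallest p this test can give.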

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

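The splits of the libraries, the list tests of the 3 comparisons and their estimated correlation were planned before the values were examined, and the other tests in this part were chosen after the results were seen. For each comparison the 6 libraries were split into 3 and 3 in all 10 ways. In High against Low, 937 genes passed against at most 4 in another split, in High against NT 2416 against at most 2, and in Low against NT 3220 against at most 1. Lists passed 8, 14 and 10 times in the real splits and at most 7, 9 and 9 times in another, so that lists are called more readily than genes when groups are mixed. In each case only 1 split of the 10, the real one, reached the real number, and 10 splits are too few for a share under 0.05.

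G2/M genes were higher and G1/S genes lower in High than in Low (median log2 0.75 and -0.35). The other genes in the same range of levels had a median of -0.0153. The values had been size-factor scaled, which centres the changes over genes beforehand, so this median cannot decide on a difference in scaling or depth. A common scaling factor would move both lists the same way. They moved in opposite directions, which argues against such a factor as the whole cause. In 41 of 50 members the NT mean lay between Low and High. This order would arise when a GFP gate parts the cells of one culture by cycle phase or size. The count asks only for the order of means. Both steps passed the test in 8 of 28 G2/M and 8 of 22 G1/S members, and 19 G2/M members did not pass in High against NT. The weight of Low that gives NT was 0.117 for the G2/M list, with NT close to High, and 0.478 for the G1/S list. The difference of 0.360 (jackknife SE 0.0487) argues against Low and High being the whole of a culture like NT. All 28 G2/M members were lower in Low than in both NT and High, and the Low mean lay between the other means in 0 of them. NT was given no vesicles, so this order argues against a response that only grows with the signal as the sole difference between the groups. NT is not described as sorted, however, so the sort and the vesicles differ together between NT and Low. A response that grows with the signal beside an effect of the sort therefore stays open, as does uptake set by cycle phase.

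NF-kappaB genes were higher in Low and High than in NT, though as a list not with an estimated correlation (adjusted p = 0.0873 and 0.0730). Monocyte genes that were low in NT had a median rise of 0 in High (largest 6.01), against a median rise of 1351 for the NF-kappaB members that rose. This argues against THP1 cells, or RNA of the same make-up as theirs, as the source of the rise. Whether the vesicles carry these marker RNAs is not known, so a selected RNA cargo was not tested. With the immediate early level as a covariate, the NF-kappaB median in High was 1.39 in place of 1.69 (camera adjusted p = 5.11e-12, with 9 of 11 members kept). In Low it was 0.996 in place of 1.322 (camera adjusted p = 5.26e-08). The fold of CXCL2 in High went from 7.39 to 2.18 (adjusted p = 0.188). This argues against handling in linear proportion to the log2 level of those genes as the whole cause. That level was 9.52 to 9.55 in NT and at least 9.87 in the Low and High libraries, so the slope is extended from these to NT. A handling effect of another shape, such as a step that Low and High share, would not be removed and stays open. The labels describe 0 NT libraries as sorted, so the vesicles and other steps that Low and High share and NT lacks cannot be told apart.

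TFRC was lower in Low and High than in NT. Its level was 9176 in NT, 2432 in Low and 2305 in High. The G2/M list had a median of 0.0854 in High and -0.72 in Low, and the G1/S list -0.18 and 0.16. Neither list was lower than NT in both groups, while TFRC was. This argues against a fall of proliferation genes common to both groups as the cause. Within each group 1 list was lower and the other higher, so a share of lower proliferation stays open there. Other mRNAs with an iron-responsive element in the 3' region, CDC14A, SLC11A2 and CDC42BPA, had a median of 0.0477 in High, and none passed in either group. The hypoxia list had a median of -0.29 in High (camera adjusted p = 4.18e-04, 0.111 with an estimated correlation). In Low its median was -0.13 (camera adjusted p = 0.0859, 0.371 with an estimated correlation). Decay through these elements and lower HIF activity therefore stay open too.

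Several groups differed between High and Low in size or direction against NT. The interferon list was 0.23 higher in High than in Low, being lower than NT in both. The NF-kappaB list was 0.27 higher, and rose in both. The YAP list, also higher than NT in both, had a difference of -0.17. The cholesterol, hypoxia and glycolysis lists had differences of -0.12, -0.13 and -0.0835, and all 3 had medians below NT in both groups. With an estimated correlation none of these 6 differences passed (adjusted p = 0.274, 0.315, 0.294, 0.274, 0.294 and 0.294). Nor did the interferon, NF-kappaB and YAP lists against NT (camera adjusted p = 0.370, 0.0730 and 0.119 in High, and 0.190, 0.0873 and 0.136 in Low). Another 50 genes changed in opposite directions against NT, PLK1 and MCM6 among them. Groups of 3 were not tested for outliers.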

How the results depend on the processing

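Alternatives planned beforehand and 3 kinds added after the results were seen (a block within the sorted libraries, leaving out the Low and High libraries numbered 3, and the immediate early level as a covariate) were run for the results they apply to, and 0 calls of named genes or lists reversed direction. DESeq2 was not run, as it needs counts. Of the named genes that passed, 31 of 57 in High against Low, 51 of 80 in High against NT and 67 of 99 in Low against NT passed in every alternative. With an estimated correlation 2, 0 and 0 lists passed, and 5 of 8, 10 of 14 and 8 of 10 lists passed in all other alternatives. In High against Low the gene count was 1505 with array quality weights, 530 to 1242 when 1 library was left out, 346 (211 higher, 135 lower) without the Low and High libraries numbered 3, 28 at a fold of at least 2 and 428 (238 higher, 190 lower) at an adjusted p below 0.01. In High against NT it was 1607 to 2322 when 1 library was left out, 1385 without the libraries numbered 3, 1146 with the covariate, 307 at a fold of at least 2 and 1171 at an adjusted p below 0.01. In Low against NT it was 1418 with the covariate, 436 at a fold of at least 2 and 1719 at an adjusted p below 0.01. The graded count was 58 to 197 when 1 library was left out and 36 without the libraries numbered 3, and the cause was not tested. With the replicate block, which follows the pairing of Low and High, the gene counts were 801, 2163 and 3003, the list counts 8, 15 and 10, the graded count 103 and the correlation of the responses 0.712, and a block within the sorted libraries gave 1270 genes and 9 lists.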

Other observations

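The families of genes in this part, and the genes named from them, were chosen after their values were seen. Their camera p-values, adjusted over these 7 families, therefore describe the patterns and are no independent test of them. Genes of actin and of the serum response factor rose in treated cells. Of 17 such genes, 16 rose and 1 fell in both High and Low against NT (median log2 0.82 and 0.85; camera adjusted p = 1.10e-16 and 4.94e-15, 0.0821 and 0.101 with an estimated correlation). The cardiac actin ACTC1 rose 4.59-fold in High, from 187 ± 35.1 to 849.8 ± 3.23 (SD, n = 3), the crosslinker ACTN1 2.04-fold, from 31443 ± 2013 to 63929.5 ± 464, and SRF itself 1.93-fold. The contractile regulator CNN1 fell 1.33-fold in High and 1.64-fold in Low.

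Homeobox genes of 2 clusters were lower in treated cells. Of 9 HOXB genes, 6 fell in each group (median log2 -1.68 in High and -1.88 in Low; camera adjusted p = 3.19e-04 and 3.43e-05, 0.0565 and 0.0286 with an estimated correlation). Of 11 HOXA genes, 4 fell in each (median log2 -0.96 and -1.02; camera adjusted p = 1.33e-04 and 1.02e-04, 0.125 and 0.102 with an estimated correlation). HOXC genes did not move as a group (camera adjusted p = 0.816 and 0.504). Replication histones fell in 17 and 23 of 43 genes (median log2 -1.52 and -1.69; camera adjusted p = 1.04e-11 and 6.79e-11, 0.344 and 0.297 with an estimated correlation), and their level also differed among the NT libraries.

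Of 19 tubulins, 7 were higher in High than in Low (median log2 0.07; camera adjusted p = 9.35e-05, 0.174 with an estimated correlation) and 8 were lower in Low than in NT (median log2 -0.23; camera adjusted p = 8.85e-04, 0.102 with an estimated correlation). In High against NT, 5 rose and 1 fell (camera adjusted p = 0.816), and the median changed sign after quantile normalization. Of 7 complement genes, C3 and C1S rose in both groups, with C1S up 3.84-fold in High and 2.96-fold in Low (camera adjusted p = 0.317 and 0.302).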
